A study of Homo sapiens with 12 samples.

How the data were processed

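Poly(A) RNA sequencing was performed on 12 SW480 libraries, 3 in each of the groups shNC, shGPD1L, Vector and OE. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was captured on oligo(dT) beads and fragmented, and complementary DNA was primed with random hexamers. No step that keeps the strand is described and strandedness is not stated, so reads of overlapping antisense genes may not have been separated. The authors deposited 2 tables of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 for each comparison. HISAT2, StringTie and DESeq2 and the genome build GRCh38 are named in the submitters' processing notes, with no versions; the role of each tool, the annotation release and any filter before deposit are not given in the sources used here. DESeq2 was not run here, because the values are not counts. Nearly every listed gene was above 0 in all 6 libraries of its table (99.7% and 99.8% of genes), so the tables hold genes that had passed a filter. Low values were not whole multiples of a common step, so reads per library could not be recovered and the depth is unknown. No interval for counting error is given, and errors are SDs or SEs between libraries.

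Libraries were grouped by their titles. The genotype labels number the gene name along the replicates, which was read as a numbering slip. The tables may have been normalized separately, so tests of each comparison were made within its table. Gene identifiers were matched to GENCODE release 29 on GRCh38, where all 12388 and 12411 annotated identifiers were found; coordinates and overlaps come from it. The tables also list 1166 and 1172 assembled genes with no annotated identifier, numbered separately in each table and therefore left out of results across tables. In both, 21 symbols had been turned into dates by spreadsheet software and were restored from their identifiers. A symbol shared by several identifiers is written with its identifier.

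Values were transformed to log2(FPKM + 1) and genes with a mean of at least 1 FPKM over the 6 libraries of a table were tested, which left out 1398 genes in the knockdown and 1375 in the overexpression. The treated line was compared with its control by limma (version 3.58.1, R 4.3.3) with an intensity trend, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. GPD1L and ATF3 were also tested with an exact permutation test of 3 against 3 libraries, which cannot give a two-sided p under 0.1. The difference of the effects, OE minus Vector less shGPD1L minus shNC, was fitted over all 12 libraries with 4 group means. The overlap of the calls is given beside that of independent lists, and the comparisons share no control libraries. A total of 30 gene lists were fixed before the data were examined, as were the comparisons, the tests and the named-gene rule. They covered ferroptosis drivers and suppressors, stress responses, metabolism, the cell cycle, p53, Wnt, interferon and inflammatory genes, epithelial and mesenchymal genes, ribosomal proteins, histones and markers of other cell types. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry; the list test on the difference of effects was added later. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

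The named genes are GPD1L, GPD1, GPD2 and ATF3; per comparison the 10 higher and 10 lower called genes with the largest fold change and non-overlapping groups; 12 ferroptosis and stress genes; up to 2 rising and 2 falling called members of each list; and the 10 genes called in opposite and 5 in the same direction with the largest smaller fold change. Some genes that this rule names are not reported here. The values of GPD1L, ATF3 and those 12 genes, and the position of shGPD1L replicate 3, were seen while the tables were inspected. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, equal library totals, median-of-ratios scaling, quantile normalization, eBayes without trend or with robust fitting, a block for the replicate number, and leaving out each library. For the gene lists, equal library totals and quantile normalization were chosen after seeing the data. None of the scalings moved the median log2 change of all genes beyond 0.07.

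The tests were checked on data simulated from the means and spreads of the real genes with 200 changed genes of log2(FPKM + 1) above 2. Of 50 genes changed by 0.5 log2 units, 22 were recovered among 12160 genes in the simulated knockdown, 34 among 12161 with the spread of its libraries other than shGPD1L replicate 3, and 41 among 12183 in the overexpression. Of 50 genes changed by 1 log2 unit, 44, 47 and 49 were recovered, with 10, 9 and 11 unchanged genes called. In these simulations the noise was independent between genes, with the same spread of a gene in both groups. In the real knockdown shGPD1L replicate 3 stood apart from the other libraries, so the recovery and false calls there may differ. The simulated difference of effects over 11198 genes used the knockdown spread without shGPD1L replicate 3, whereas the real fit included that library. There 281 of 285 genes changed by at least 1 were recovered, with 15 unchanged genes called. Recovery in the real fit may therefore be lower. For the gene lists a separate simulation used the mean of each gene, with noise of the same size that was independent between genes. A simulated rise of the p53 targets by 0.5 in the overexpression was found, with 0 of the other 25 lists passing. In the real overexpression the estimated inter-gene correlation ran from -0.142 to 0.688 over the lists. The simulation therefore says nothing about false calls of lists whose genes vary together.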

Results

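Gene expression was measured by poly(A) RNA sequencing in SW480, a cell line established from a human colon adenocarcinoma, after GPD1L had been lowered or raised. GPD1L encodes glycerol-3-phosphate dehydrogenase 1-like, a relative of the cytosolic enzyme GPD1 that interconverts glycerol-3-phosphate and dihydroxyacetone phosphate. A line carrying a short hairpin RNA against GPD1L (shGPD1L) was compared with a line carrying a control hairpin (shNC), and a line overexpressing GPD1L (OE) with a line carrying the vector (Vector). Each of the 4 groups had 3 libraries. Each change of GPD1L was thus studied in a single group against a single control group. Other effects of the hairpin, or differences between the lines, cannot be told apart from effects of the GPD1L level. The authors' tables listed 13554 genes for the knockdown and 13583 genes for the overexpression, in FPKM. The listed values of a library summed to between 421714 and 444794 FPKM, and the number of reads behind them is unknown. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Fold changes are differences of log2(FPKM + 1), which understate the change of genes with low FPKM, and adjusted p-values are from limma with the Benjamini-Hochberg adjustment unless another test is named.

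The first comparison asked which transcripts differ when GPD1L is lowered. GPD1L (ENSG00000152642, chromosome 3, 32105689 to 32168713, plus strand, GRCh38, a protein-coding gene) was listed at 8.68, 8.01 and 9.10 FPKM in the shNC libraries and at 1.55, 1.26 and 2.23 FPKM in the shGPD1L libraries. Its mean fell from 8.60 ± 0.55 to 1.68 ± 0.49 FPKM (SD, n = 3 each), a log2 change of -1.85 (SE 0.14, adjusted p = 0.00675). ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777, plus strand), a stress-induced transcription factor that the series title names together with ferroptosis, was lower in 3 of 3 shGPD1L libraries. Its mean was 12.8 ± 0.54 FPKM in shNC and 6.99 ± 1.5 FPKM in shGPD1L (SD, n = 3 each), a log2 change of -0.81 (SE 0.13, adjusted p = 0.048). The exact two-sided permutation test of 3 against 3 libraries gave p = 0.1 for both genes, the smallest value this design allows. The ATF3 call passed the threshold in 4 of 16 alternative settings, with adjusted p-values from 0.0218 to 0.245; without shNC replicate 1, 2 or 3 or shGPD1L replicate 2 they were 0.245, 0.195, 0.237 and 0.106. The GPD1L call was lost without shNC replicate 1, 2 or 3, at adjusted p-values of 0.0677, 0.0522 and 0.0836, within a range of 0.000402 to 0.0836 over its 16 alternatives. Of the related enzymes, mitochondrial GPD2 was at 8.21 ± 0.93 FPKM in shNC and 8.03 ± 0.86 FPKM in shGPD1L (SD, n = 3 each; adjusted p = 0.93), and GPD1, at a mean of 0.693 FPKM, lay below the expression filter.

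**Figure D1:**
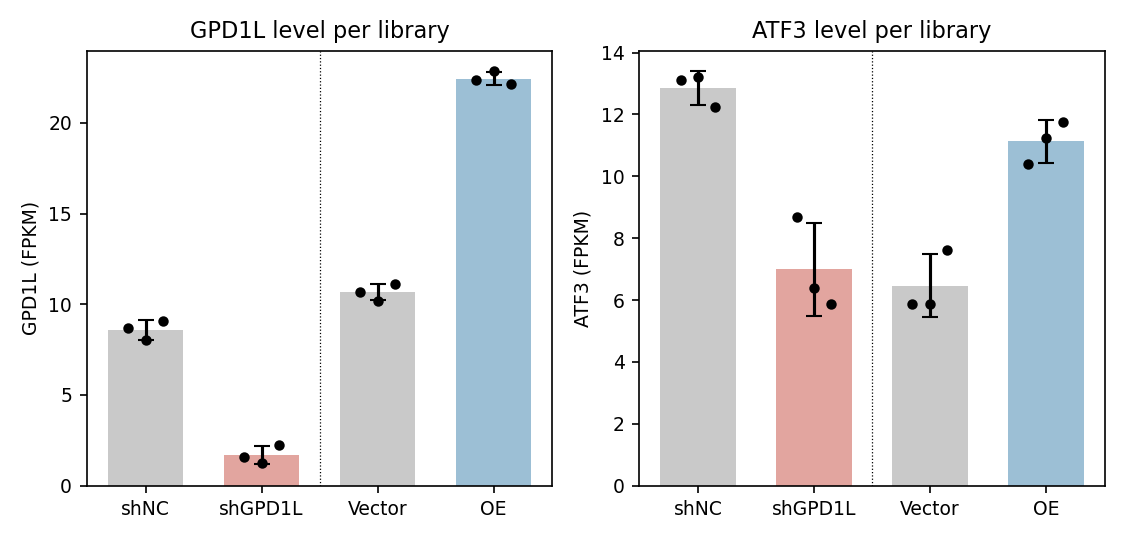
FPKM of GPD1L (left) and ATF3 (right) in the 4 groups; points are libraries, bars are group means and error bars are SD of 3 libraries, and the dotted line separates the tables. GPD1L had a mean of 1.68 FPKM in shGPD1L against 8.60 in shNC and 22.4 in OE against 10.7 in Vector, and ATF3 was lower in every shGPD1L library and higher in every OE library than in its controls.

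Of 12156 genes tested in the knockdown, 72 were called, 14 higher and 58 lower. On the log2(FPKM + 1) scale 11 of them changed at least 2-fold, or 7 with the filter at 5 FPKM. That count was 16 and 15 with pseudocounts of 0.1 and 0.5. After GPD1L, the largest falls with non-overlapping groups were those of the trypsinogen genes PRSS2 and PRSS1, with log2 changes of -1.63 and -1.39. These paralogs are near-identical in sequence, so their reads may be divided between them with error. IGFL2, an insulin growth factor-like family member, fell from 43.8 ± 2.84 to 17.4 ± 2.48 FPKM (SD, n = 3 each). MYBPH (log2 change -1.22), TNFRSF19 (-1.22), PRR9 (-1.08), SH3BGR (-1.07), the adhesion glycoprotein gene CEACAM6 (-1.04) and the cytokine gene IL32, which fell from 13.9 ± 2.0 to 6.44 ± 1.02 FPKM, completed the 10 largest falls. SH3BGR shares exons with the read-through gene WRB-SH3BGR. The neuropeptide precursor gene VGF rose from 51.8 ± 5.69 to 112 ± 10.0 FPKM (SD, n = 3 each; log2 change 1.10, adjusted p = 0.0134). It was the 1 gene called with a rise of at least 2-fold on the log2(FPKM + 1) scale. In plain FPKM the ratio of means was also above 2 for IER5L (2.09) and TRIT1 (2.08). The other 9 leading rises were IER5L (log2 change 0.99), TRIT1 (0.93), the transcriptional inhibitor ID3 (0.71), the circadian repressor PER1 (0.70), GIT1 (0.67), SAMD5 (0.67), RPUSD4 (0.66), ZNF641 (0.63) and DBP (0.62), a clock-controlled transcription factor. RPUSD4 and DBP overlap antisense genes, FAM118B and SPHK2, whose reads cannot be told apart where the strand is not kept.

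The library shGPD1L replicate 3 stood apart from the other 5 libraries of its table on the first principal component, at 29.1 against values from -12.1 to 0.32. The median SD per gene was 0.151 on the log2 scale in shGPD1L and 0.0894 in shNC, each over 3 libraries. Without this replicate it was 0.0780 in shGPD1L. That value is over 2 libraries, where a median SD runs lower, so it cannot be set directly against the others. Without it, 609 genes were called, 219 higher and 390 lower, and all 72 genes were among them with the same direction. Without shNC replicate 1, 2 or 3 the counts were 1, 0 and 0 genes, with 1249, 1408 and 1126 genes at an unadjusted limma p under 0.05, and the calls of all 34 called named genes ended in each case. Without shGPD1L replicate 1 or 2 the counts were 8 and 7 genes. The counts of genes changed at least 2-fold without shNC replicates 1 to 3 were 1, 0 and 0, and without shGPD1L replicate 1 or 2 they were 7 and 7. With quantile normalization 25 genes were called, of which 32% were higher, against 19.4% in the unscaled values.

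**Figure D2:**
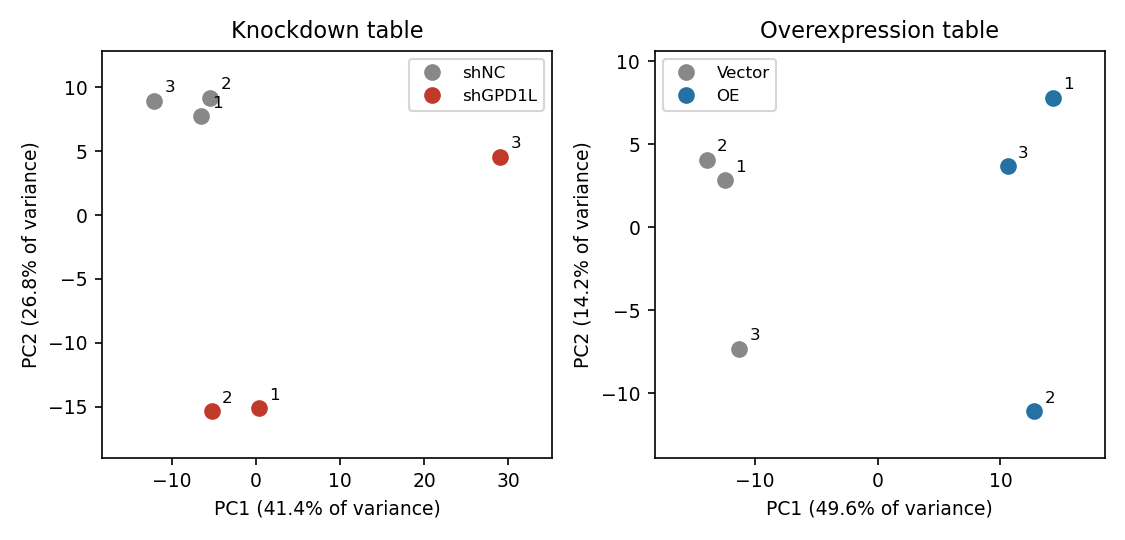
First 2 principal components of log2(FPKM + 1) in the knockdown table (left) and the overexpression table (right); each point is a library with its replicate number, and axes give component scores and the share of variance. In the knockdown table shGPD1L replicate 3 lies at 29.1 on the first component, which held 41.4% of the variance, and in the overexpression table the first component, with 49.6%, separates OE from Vector.

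Targets of p53, a transcription factor that is mutated in SW480, were lower in the knockdown. Of 26 lists tested 8 passed camera at its preset correlation, 0 with an estimated correlation and 3 with fry (p53 targets, replication-dependent histones and ferroptosis drivers, each toward lower values), and the camera count was 13 without shGPD1L replicate 3 and 5 without shGPD1L replicate 2. Of 22 measured p53 targets, 2 fell over all genes tested and 10 fell when adjusted over the list alone, with none higher in either count. FAS, a death receptor gene that overlaps ACTA2 on the other strand, fell from 12.7 ± 1.23 to 6.85 ± 0.67 FPKM (SD, n = 3 each), and RRM2B, a ribonucleotide reductase subunit gene, from 17.0 ± 0.50 to 11.6 ± 0.885. The p53 list had a camera adjusted p = 0.000132 (adjusted p = 0.302 with an estimated correlation). Relative to the shNC mean, the list mean was -0.279, -0.243 and -0.247 log2 units in shGPD1L replicates 1, 2 and 3. Replication-dependent histone genes, whose transcripts mostly lack the poly(A) tail used for capture, were also lower, with 2 of 9 members called and 2 when adjusted over the list alone, HIST1H2BK (log2 change -0.76) and HIST2H2AA3 (-0.58), the second of which has a near-identical copy in HIST2H2AA4. The histone list had an adjusted camera p of 0.031 (adjusted p = 0.433 with an estimated correlation), at -0.207, -0.34 and -0.217 in shGPD1L replicates 1 to 3, and was lost without shGPD1L replicate 2 (adjusted p = 0.165). Of 25 interferon-stimulated genes 1 fell, also when adjusted over the list alone, the chemokine gene CXCL10 (log2 change -0.74). That list passed toward lower values (adjusted p = 0.00254; adjusted p = 0.585 with an estimated correlation), at -0.239, -0.196 and -0.0777 in shGPD1L replicates 1 to 3, and was lost without shGPD1L replicate 2 (adjusted p = 0.0591).

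Genes encoding endoplasmic reticulum (ER) chaperones and ER-associated degradation factors passed camera toward higher values (adjusted p = 0.000177; adjusted p = 0.306 with an estimated correlation). Of the 22 members 0 were called by limma over all genes tested, with 9 at an unadjusted p under 0.05, while 7 were higher and 1 lower when adjusted over the list alone. The list mean lay at 0.147, 0.187 and 0.0607 in shGPD1L replicates 1 to 3, and without replicate 3, 6 members were called higher. NRF2 targets, genes of the antioxidant response, passed toward higher values (adjusted p = 0.00705; adjusted p = 0.682 with an estimated correlation). Of 25 members 0 were called by limma, also when adjusted over the list alone, and 4 had an unadjusted p under 0.05. Their mean lay at 0.619 in shGPD1L replicate 3 and at -0.0715 and -0.0147 in replicates 1 and 2, and without replicate 3 the list mean was -0.04 (adjusted p = 0.779); with quantile normalization the list had an adjusted p of 0.0554. Immediate-early genes passed toward higher values (adjusted p = 0.000141; adjusted p = 0.682 with an estimated correlation), at 0.658 in replicate 3 against 0.113 and 0.0536, and the 1 called member of 26, ATF3, fell, with 1 higher and 1 lower when adjusted over the list alone. Mitosis genes passed toward higher values with 0 of 26 members called in either count and 1 at an unadjusted p under 0.05 (adjusted p = 0.00312; adjusted p = 0.682 with an estimated correlation). They lay at 0.253 and 0.197 in replicates 1 and 2 and -0.168 in replicate 3. That call was lost without shGPD1L replicate 1 (adjusted p = 0.169) or 2 (adjusted p = 0.0998). Without shGPD1L replicate 3 the mitosis list passed camera (adjusted p = 7.19e-11, or 0.218 with an estimated correlation). There 6 of 26 members were called higher, and 13 when adjusted over the list alone. Cytosolic ribosomal protein genes passed toward higher values with 0 of 73 members called in either count and 5 at an unadjusted p under 0.05 (adjusted p = 0.000177; adjusted p = 0.682 with an estimated correlation). They lay at 0.0435, 0.277 and -0.113 in shGPD1L replicates 1 to 3, and the call was lost without shGPD1L replicate 2 (adjusted p = 0.414, list mean -0.03) and with quantile normalization (adjusted p = 0.279). Without shGPD1L replicate 3 the ribosomal list passed camera (adjusted p = 3.7e-08, or 0.474 with an estimated correlation). There 1 of 73 members was called higher, and 0 when adjusted over the list alone.

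Of 22 measured ferroptosis drivers 1 fell in the knockdown, ATF3, and 3 fell when adjusted over the list alone. The driver list did not pass camera (adjusted p = 0.0659) and passed fry toward lower values (adjusted p = 0.044), which tests whether its genes moved on balance one way and not against other genes. Without shGPD1L replicate 3 the driver list passed camera toward lower values (adjusted p = 0.0469; adjusted p = 0.324 with an estimated correlation), its mean lying at -0.112, -0.113 and -0.181 in shGPD1L replicates 1 to 3. Of 28 measured suppressors 0 were called by limma in either count, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.154, fry adjusted p = 0.644), and the list lay at 0.192 in replicate 3 against -0.0413 and -0.018. The cystine transporter gene SLC7A11 was at 19.2 ± 1.36 FPKM in shNC and 17.5 ± 2.86 FPKM in shGPD1L (SD, n = 3 each; adjusted p = 0.626). The phospholipid hydroperoxidase gene GPX4 was at 238 ± 9.35 and 272 ± 14.7 FPKM (adjusted p = 0.304), and ACSL4, an acyl-CoA synthetase gene, at 14.3 ± 0.17 and 12.1 ± 0.41 FPKM (adjusted p = 0.209). PTGS2 had a log2 change of 0.60 (adjusted p = 0.107), CHAC1 of -0.37 (0.244), HMOX1 of 0.36 (0.481), NCOA4 of -0.21 (0.253), FTH1 of 0.14 (0.56), AIFM2 of 0.13 (0.477), TFRC of 0.09 (0.822), LPCAT3 of 0.04 (0.896) and DDIT3 of 0.03 (0.907). Without shGPD1L replicate 3 PTGS2 was called higher at a log2 change of 0.46 (adjusted p = 0.0314, within a range of 0.0314 to 0.386 over its alternatives), and the log2 change was -0.22 for CHAC1, 0.0758 for HMOX1, 0.0516 for FTH1, 0.28 for TFRC and -0.25 for SLC7A11, none of them called. Without any 1 library that of HMOX1 ran from 0.0758 to 0.55 and that of SLC7A11 from -0.25 to -0.0411, the 0.55 and the -0.0411 being without shGPD1L replicate 1. The ATF4-ATF3 stress response list had 1 called member of 35, ATF3, and 2 lower when adjusted over the list alone (adjusted p = 0.116).

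The second comparison asked which transcripts differ when GPD1L is raised. GPD1L was listed at 10.7, 10.2 and 11.1 FPKM in the Vector libraries and at 22.3, 22.8 and 22.1 FPKM in the OE libraries. Its mean rose from 10.7 ± 0.45 to 22.4 ± 0.37 FPKM (SD, n = 3 each), a log2 change of 1.01 (SE 0.052, adjusted p = 4.74e-05). ATF3 rose from 6.46 ± 1.01 to 11.1 ± 0.69 FPKM (SD, n = 3 each), a log2 change of 0.71 (SE 0.098, adjusted p = 0.00257), and was higher in 3 of 3 OE libraries. The exact two-sided permutation test gave p = 0.1 for each. GPD2 was at 8.30 ± 0.60 FPKM in Vector and 7.34 ± 0.27 FPKM in OE (SD, n = 3 each; adjusted p = 0.135), and GPD1, at a mean of 0.442 FPKM, was below the filter.

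Of 12208 genes tested in the overexpression, 2740 were called, 1484 higher and 1256 lower, and 29 changed at least 2-fold, 4 higher and 25 lower; that count was 79 and 48 with pseudocounts of 0.1 and 0.5 and 13 with the filter at 5 FPKM. The median log2 change among called genes was 0.30 in size. The dipeptidase gene DPEP1 fell from 32.4 ± 1.93 to 11.5 ± 0.91 FPKM and the folate receptor gene FOLR1 from 38.1 ± 0.73 to 15.7 ± 1.70 FPKM (SD, n = 3 each). The kallikrein genes KLK11 and KLK14 fell by 1.37 and 1.36 on the log2 scale, and belong to a family of similar sequence. SERPINA5 (log2 change -1.21), the fatty acid-binding protein gene FABP1 (-1.19) and the angiotensinogen gene AGT (-1.18) were also among the largest falls. The circadian repressor NR1D1 rose from 17.5 ± 0.38 to 48.9 ± 2.47 FPKM (SD, n = 3 each; log2 change 1.43, adjusted p = 1.71e-05); it overlaps THRA on the other strand. Further rises were those of the uridine phosphorylase gene UPP1 (log2 change 0.98), the clock repressor BHLHE41 (0.97), and the histone genes HIST1H2BK (0.92) and HIST1H1C (0.88). A further set of leading genes overlap another listed gene on the same strand, with which reads may be shared. They were one of the MATR3 identifiers (MATR3.ENSG00000015479, log2 change 2.88), TRIM39-RPP21 (1.27) and one of the ATXN7 identifiers (ATXN7.ENSG00000163635, 0.92) among the rises, and AC118553.2 (-2.41) and SYS1-DBNDD2 (-1.21) among the falls. With library totals set equal, 3418 genes were called, 71.4% of them higher, against 54.2% in the unscaled values. With median-of-ratios scaling 1252 were higher and 1465 lower (46.1% higher) and with quantile normalization 1271 and 1294 (49.6%), so the direction of the majority depends on the scaling. Without Vector replicate 1 or 2, 1679 and 1550 genes were called, and without OE replicate 1 or 2, 1801 and 1749. Of 118 named genes called in the overexpression, 24 lost the call without at least 1 library, among them TRIM39-RPP21 (without Vector replicates 1 or 3 or OE replicates 2 or 3, adjusted p up to 0.121) and ATXN7.ENSG00000163635 (without OE replicates 1 or 2, adjusted p up to 0.0553).

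The ATF4-ATF3 stress response list was higher in the OE line, 1 of 16 lists of 27 tested that passed camera at its preset correlation; 0 passed with an estimated correlation and 17 with fry, which included the ferroptosis drivers and the lysosome and autophagy genes and left out the respiratory chain list. Of its 35 measured members 17 rose and 1 fell, and 18 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.96e-06; adjusted p = 0.0967 with an estimated correlation). GDF15, a stress-induced cytokine gene, rose from 323 ± 20.6 to 541 ± 24.7 FPKM (SD, n = 3 each), and DDIT3, encoding the transcription factor CHOP, rose from 67.7 ± 6.40 to 101 ± 2.56 FPKM, while the tryptophanyl-tRNA synthetase gene WARS fell (log2 change -0.15, adjusted p = 0.0351). ER chaperone and degradation genes moved the other way, with 2 of 22 members higher and 12 lower, and 2 higher and 13 lower when adjusted over the list alone (adjusted p = 2.78e-05; adjusted p = 0.0967 with an estimated correlation). MANF fell from 71.9 ± 4.60 to 47.4 ± 1.60 FPKM and SDF2L1 by 0.50 on the log2 scale, whereas the ER stress sensor gene ERN1 (0.39) and DNAJB9 (0.26) rose. The call of WARS was lost without any 1 library (adjusted p up to 0.0933), that of DNAJB9 without any 1 library but OE replicate 2 (up to 0.0834), and that of SDF2L1 without Vector replicate 1 or 2 or OE replicate 1 (up to 0.0573). Of 13 heat shock genes 4 fell and 1 rose, and 4 fell and 2 rose when adjusted over the list alone; HSPA1A and HSPA1B, which share nearly all of their coding sequence, fell by 0.92 and 0.90 on the log2 scale. That list passed at an adjusted p of 0.0327 (adjusted p = 0.331 with an estimated correlation), and was lost without Vector replicate 2 (adjusted p = 0.0575), with equal totals (0.0591) and with quantile normalization (0.0636).

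p53 targets were higher in the OE line, with 11 of 21 measured members called higher in both counts and none lower (adjusted p = 0.000473; adjusted p = 0.183 with an estimated correlation). CDKN1A, encoding the cell cycle inhibitor p21, rose from 104 ± 3.21 to 163 ± 6.24 FPKM and MDM2, encoding the p53 ubiquitin ligase, from 8.31 ± 0.11 to 12.4 ± 0.72 FPKM (SD, n = 3 each). Of 24 DNA replication and G1/S genes 15 fell and 1 rose, and 16 fell and 1 rose when adjusted over the list alone (adjusted p = 2.44e-08; adjusted p = 0.0967 with an estimated correlation). FEN1, the flap endonuclease gene, fell from 29.8 ± 3.03 to 19.5 ± 0.83 FPKM, and the replicative helicase subunit gene MCM3 from 53.9 ± 2.11 to 36.1 ± 1.44 FPKM. FEN1 overlaps FADS2. RRM2, which overlaps AC007240.1, rose by 0.15 on the log2 scale (adjusted p = 0.0499), a call lost without Vector replicate 1, 2 or 3 or OE replicate 1 or 2 (adjusted p up to 0.146). Of 26 mitosis genes 14 rose and 0 fell, and 17 rose and 1 fell when adjusted over the list alone (adjusted p = 5.75e-06; adjusted p = 0.0967 with an estimated correlation), including the kinetochore genes CENPE (log2 change 0.45) and CENPF (0.42). Of 9 genes of the histone list 6 rose, and 8 when adjusted over the list alone (adjusted p = 2.87e-05; adjusted p = 0.0967 with an estimated correlation). They include H1F0 (log2 change 0.33), a linker histone gene that does not depend on replication and was singled out after its value was seen.

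Interferon-stimulated genes were lower, with 18 of 27 members called lower and none higher, and 19 lower when adjusted over the list alone (adjusted p = 3.04e-09; adjusted p = 0.0967 with an estimated correlation). The antiviral genes BST2, which fell from 37.2 ± 1.52 to 19.0 ± 1.92 FPKM, and MX2, with a log2 change of -0.59, had the largest falls of the list. Of 73 cytosolic ribosomal protein genes 43 fell, and 62 when adjusted over the list alone (adjusted p = 1.3e-19; adjusted p = 0.183 with an estimated correlation), among them RPL14 (log2 change -0.60) and RPL28 (-0.43). The call of RPL14 was lost without Vector replicate 1 or 2 (adjusted p up to 0.0598). Targets of Wnt and beta-catenin fell in 8 of 19 cases, and 10 fell and 1 rose when adjusted over the list alone (adjusted p = 9.39e-05; adjusted p = 0.331 with an estimated correlation). NOTUM, a secreted Wnt inhibitor gene, fell from 2.63 ± 0.096 to 0.76 ± 0.12 FPKM, and the intestinal stem cell factor gene ASCL2 had a log2 change of -0.79. Of 23 cholesterol synthesis and uptake genes 8 fell and 1 rose, and 10 fell and 1 rose when adjusted over the list alone (adjusted p = 0.00024; adjusted p = 0.331 with an estimated correlation), with INSIG1 (log2 change -0.45) among the falls. Immediate-early genes rose in 12 of 25 cases and fell in 1, and 13 rose and 2 fell when adjusted over the list alone (adjusted p = 0.000858; adjusted p = 0.331 with an estimated correlation), with DUSP5 (log2 change 0.75) and ATF3 highest and MYC (-0.38) lower. Of 13 mitochondrially encoded genes 6 fell, and 8 when adjusted over the list alone, MT-ND1 (log2 change -0.58) and MT-ND2 (-0.33) the most (adjusted p = 2.78e-05; adjusted p = 0.373 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.774).

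**Figure D3:**
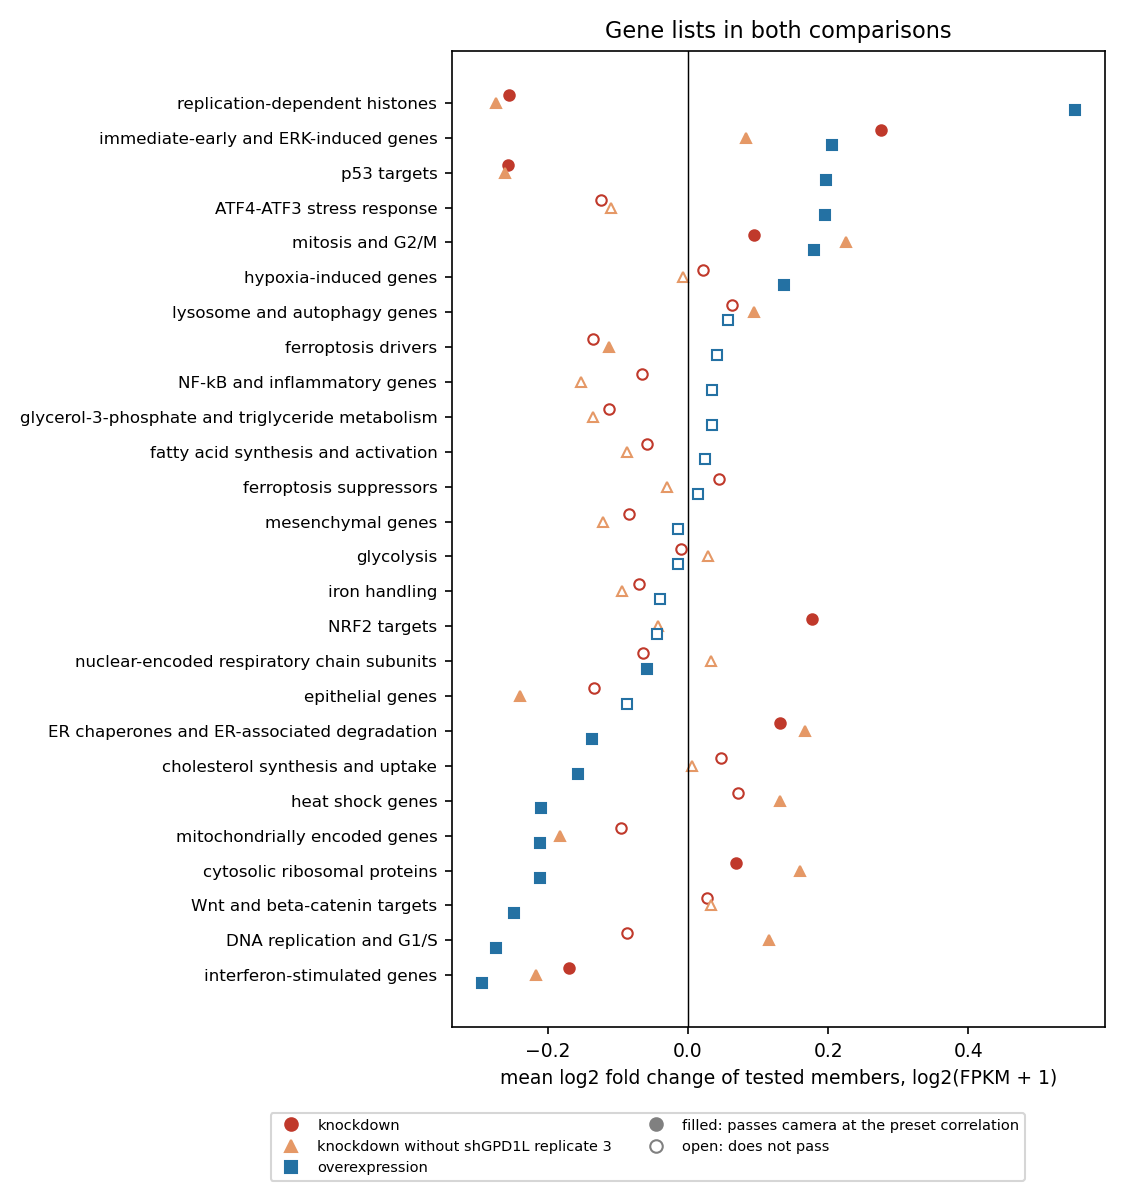
Mean log2 fold change of the tested members of each gene list in the knockdown, the knockdown without shGPD1L replicate 3 and the overexpression; filled symbols pass camera at the preset correlation. Lists for p53 targets and histones lie below 0 in the knockdown and above 0 in the overexpression, and none of the filled symbols passes with an estimated correlation.

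Ferroptosis genes moved both ways in the OE line. Of 22 measured drivers 5 rose and 4 fell, and 7 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.505). The driver list passed fry toward higher values (adjusted p = 0.0153), the reverse of its direction in the knockdown, with a mean at 0.0458, 0.0345 and 0.0421 log2 units in OE replicates 1 to 3. ATF3, with a log2 change of 0.71, is a member of this list. Fry does not subtract the shift of all genes, whose median log2 change was 0.0243, so the reversal may owe much to ATF3 and that shift. Of 29 measured suppressors 6 rose and 7 fell, and 9 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.612, fry adjusted p = 0.181). SLC7A11 rose from 45.4 ± 1.67 to 63.2 ± 4.54 FPKM (SD, n = 3 each; adjusted p = 0.00186), as did GCLM, a subunit gene of the glutathione-synthesising ligase (log2 change 0.42), while HSPB1 (-0.46) and AKR1C3 (-0.55) fell. PTGS2 rose by 0.79, ACSL4 by 0.26 and the ferritin receptor gene NCOA4 by 0.23 on the log2 scale, whereas DPP4 (-0.61), LPCAT3 (-0.31), HMOX1 (-0.30) and TFRC (-0.17) fell. GPX4 was at 269 ± 8.30 FPKM in Vector and 258 ± 12.5 FPKM in OE (adjusted p = 0.397). CHAC1 had a log2 change of 0.12 (adjusted p = 0.157), AIFM2 of 0.07 (0.449) and FTH1 of 0.07 (0.329). The TFRC call was lost without Vector replicate 1, 2 or 3 or OE replicate 2 or 3 (adjusted p up to 0.1), and that of HMOX1 without Vector replicate 1 or 2 or OE replicate 3 (up to 0.0587). LPCAT3 and DDIT3 overlap genes on the other strand, EMG1 and both MARS and MBD6, as do FTH1 and AIFM2 with BEST1 and H2AFY2.

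The third comparison asked whether the 2 manipulations moved genes in opposite directions. Of 11208 annotated genes tested in both tables, 18 were called in opposite directions, against 8.40 for independent lists of these sizes, and 12 in the same direction, against 7.49. The 18 include GPD1L itself, which was manipulated in opposite ways. They also include both HIST2H2AA3 and HIST2H2AA4, near-identical copies that may share reads, so the 18 are not all separate results. The counts were 9 and 8 with median-of-ratios scaling, against 5.17 and 5.46 for independent lists, 5 and 4 with quantile normalization, against 2.50 and 2.52, and 8 and 7 without the trend, against 5.00 and 4.49. GPD1L, ATF3, HIST1H2BK, HIST2H2AA3, HIST2H2AA4, KLHL5, MMP1 and NEK7 were lower in the knockdown and higher in the overexpression, and VGF and ID3 the reverse. KLHL5 had log2 changes of -0.51 and 0.52, the collagenase gene MMP1 of -0.63 and 0.45 and the kinase gene NEK7 of -0.73 and 0.40. PER1 rose in both comparisons, by 0.70 and 0.86 on the log2 scale, and DBP by 0.62 and 0.86, while the chemokine gene CXCL11 (-0.79 and -0.74), LAT2 (-0.71 and -0.64) and PTAFR (-0.64 and -0.50) fell in both. Without shGPD1L replicate 3 the counts were 124 opposite, against 69.3 for independent lists, and 100 in the same direction, against 65.9. Without shNC replicate 1, 2 or 3 both counts were 0, where limma called 1, 0 and 0 knockdown genes. Without shGPD1L replicate 1 the counts were 3 and 0, and without shGPD1L replicate 2 they were 1 and 0. Across the genes the fold changes had a Pearson correlation of -0.078 and a Spearman correlation of -0.092; genes are not independent replicates.

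The difference between the effects was tested in 1 fit of all 12 libraries. ATF3 had an overexpression effect 1.52 above its knockdown effect on the log2 scale (SE 0.18, adjusted p = 0.000619), and GPD1L one 2.86 above (SE 0.15, adjusted p = 2.3e-06). The controls themselves differed in ATF3, at 12.8 FPKM in shNC and 6.46 FPKM in Vector, with GPD1L at 8.60 and 10.7 FPKM. ATF3 in shGPD1L, at 6.99 FPKM, was near its Vector level. Across the 4 groups the listed ATF3 values thus did not follow those of GPD1L, though the tables may have been normalized separately. The effects differed for 1584 genes, 1024 with a higher and 560 with a lower value in the overexpression. This count was 2572 without shGPD1L replicate 3, 898 without shNC replicate 3, 986 and 844 without Vector replicate 1 or 2, and 790 and 940 without OE replicate 1 or 2. Of 26 lists 9 passed camera on this difference, and 3 of these with an estimated correlation. They were p53 targets (mean difference 0.46, adjusted p = 0.0164 with an estimated correlation), replication-dependent histones (0.87, 0.0164) and ER chaperone and degradation genes (-0.27, 0.0212). The ATF4-ATF3 stress response had a mean difference of 0.32 (adjusted p = 3.21e-05; adjusted p = 0.0938 with an estimated correlation). Cytosolic ribosomal proteins (-0.28), cholesterol synthesis and uptake (-0.20), Wnt and beta-catenin targets (-0.29), DNA replication (-0.19) and heat shock genes (-0.28) passed at the preset correlation, with adjusted p = 0.409, 0.228, 0.228, 0.873 and 0.701 with an estimated correlation. The ferroptosis drivers (adjusted p = 0.15) and suppressors (0.595) did not pass camera on the difference, and fry was not run on it.

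**Figure D4:**
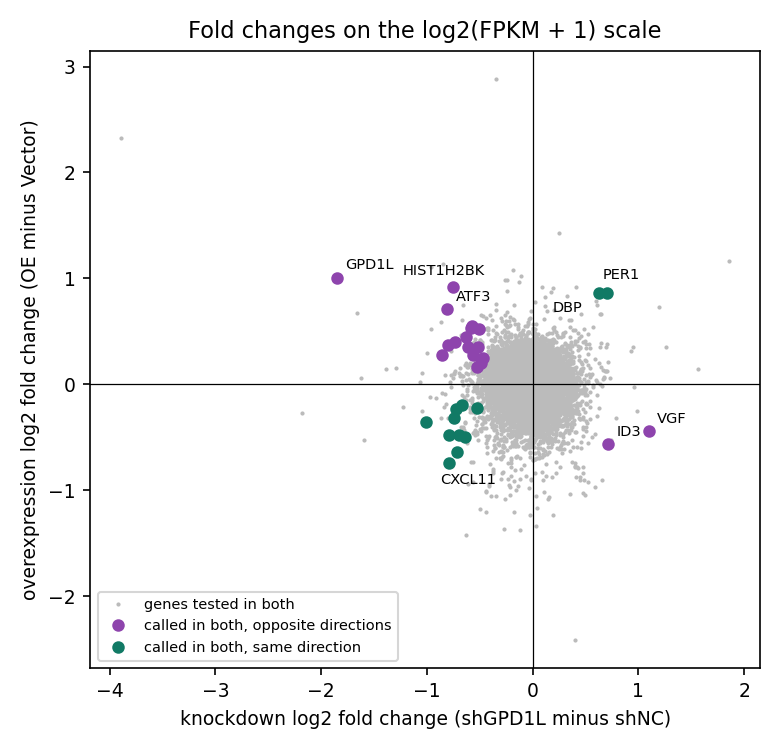
Log2 fold change in the overexpression (vertical) against that in the knockdown (horizontal) for the 11208 annotated genes tested in both; grey points are genes, purple points the 18 called in opposite directions and green points the 12 called in the same direction. GPD1L, ATF3 and HIST1H2BK lie at upper left, VGF and ID3 at lower right, and PER1 and DBP at upper right.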

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

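The test of shGPD1L replicate 3 and the list test on the difference of the effects were chosen only after the result was seen. The overexpression and knockdown effects differed, by the contrast itself, for 1584 genes. GPD1L had a difference of 2.86 on the log2 scale and ATF3 one of 1.52, both past the threshold of the same contrast. Among the lists that passed this contrast with an estimated correlation, the mean difference was -0.27 for ER chaperone and degradation genes, 0.46 for p53 targets and 0.87 for replication-dependent histones, of which 7 genes were tested in both tables. Of 100 drawn splits of the 12 libraries, 1, the real one, gave as many genes for the difference, and the highest of the others gave 270. Each of the others mixed treated and control libraries in at least 1 comparison. The count was thus not matched by mixed groupings, but a large effect in the overexpression alone could contribute to this. These splits do not tell whether the 2 effects are opposed. For genes called in opposite directions 1 of 100 splits, the real one, gave as many as 18. The others gave 0 genes called in both comparisons, in opposite or in the same direction, so these splits say nothing about whether the calls are opposed. A correlation as far below 0 as -0.078 came from 7 of 100 splits, the lowest of the others being -0.125, so chance is not excluded for the correlation of the fold changes.

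Within each comparison the 6 libraries make 10 splits, too few for a share under 0.05. In the knockdown the real split called 72 genes and the highest other 2, and for genes changed at least 2-fold 11 against 2; in each case 1 split, the real one, reached the count. In the overexpression the real split called 2740 genes and the highest other 1, and 29 genes at least 2-fold against 1, again 1 split each. For lists passing camera the overexpression had 16 against a highest other of 9, reached by 1 split. In the knockdown 4 of 10 splits had at least the 8 lists of the real one, the highest being 13. The 3 other splits, with 11, 12 and 13 lists, each put shGPD1L replicate 3 with 2 shNC libraries, which points to a structure of the samples.

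Fewer genes were called in the knockdown, 72, than in the overexpression, 2740. Without shGPD1L replicate 3 the knockdown count was 609, above the count of all 6 libraries, while leaving out any other library of the table gave 0 to 8, so the spread brought by this library may account for part of the gap. It does not close it, since the overexpression gave 1550 to 1980 genes without 1 of its libraries. The SD of the fold changes after subtraction of the mean squared SE was 0.188 in the knockdown without that replicate and 0.203 to 0.216 in the overexpression without 1 library, so somewhat smaller fold changes in the knockdown stay open as well. Why shGPD1L replicate 3 stands apart was not tested.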

How the results depend on the processing

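Quantile normalization and equal totals of the gene lists were chosen only after the data were seen. For named genes 2279 of 2629 values under an alternative kept their direction and their side of the threshold, 339 lost the call (208 of these in the knockdown), 10 changed sign and 1 gained a call; for gene lists 261 of 312 kept both and 50 lost the call. The correlation of the fold changes stayed between -0.107 and -0.05 without any 1 library. When 1 library was left out, the knockdown GPD1L change ran from -2.0 without shGPD1L replicate 3 to -1.74 without replicate 2. With pseudocounts of 0.1 and 0.5 it was -2.32 and -2.08. ATF3 in the knockdown missed the threshold at a log2 change of -0.89 with a pseudocount of 0.1, -0.85 with 0.5, -0.81 with no filter, -0.80 with equal totals, -0.77 with median-of-ratios scaling, -0.77 with quantile normalization and -0.81 without the trend, and ran from -0.96 to -0.71 without 1 library. With quantile normalization 25 knockdown genes were called, 5 in opposite directions and 4 in the same direction, and GPX4 in the overexpression was at 0.0418 and GPD2 in the knockdown at 0.0130. With median-of-ratios scaling GPD2 was at 0.0123 and 9 genes were called in opposite directions; without the trend 8 were, and 7 in the same direction. The filter at 5 FPKM, which tests fewer genes, left 7 genes changed at least 2-fold in the knockdown and 13 in the overexpression, and pseudocounts of 0.1 and 0.5, which compress low genes less, gave 79 and 48 in the overexpression. With an estimated correlation 0 knockdown and 0 overexpression lists passed, and with fry 3 knockdown lists. Beyond these constructions the cause was not tested.

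Without 1 library the knockdown counts ran from 0 to 609 genes, from 0 to 15 genes at least 2-fold and from 5 to 13 lists, the overexpression count from 1550 to 1980, the opposite calls from 0 to 124, the calls in the same direction from 0 to 100 and the difference of effects from 790 to 2572. In the knockdown GPD2 ran from -0.0805 to 0.0539, TFRC from -0.0554 to 0.280, DDIT3 from -0.0330 to 0.0776, LPCAT3 from -0.0185 to 0.119 and the NRF2 list mean from -0.0431 to 0.302. The replicate numbers showed no sign of pairing the samples: correlations of same-numbered deviations were -0.0155, -0.18 and -0.163 in the knockdown and 0.0222, -0.0607 and -0.0363 in the overexpression. Those of different numbers ran from -0.0689 to 0.25 in the knockdown and from -0.0331 to 0.0709 in the overexpression. With so few libraries these values cannot exclude that samples were prepared in pairs. With a replicate block 3 knockdown genes were called, 3 of them at least 2-fold, ATF3 stayed at -0.81 with an adjusted p of 0.195, 31 named genes of the knockdown, ATF3 included, and 11 of the overexpression lost the call, the overexpression heat shock list missed the threshold at an adjusted p of 0.0508, the opposite calls were 1, the calls in the same direction 0 by limma, and the difference of effects 483. As depth is unknown, the precision of low FPKM cannot be stated.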

Other observations

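The test of the GPD1L level against the clock genes, and the list of clock genes, were chosen only after the result was seen. Several gene groups not described so far were measured. In the OE line 9 of 22 hypoxia-induced genes rose and 2 fell, ANKRD37 (log2 change 0.70) and DDIT4 (0.52) rising and CA12 (-0.70) and EGLN3 (-0.26) falling (camera adjusted p = 0.0327; adjusted p = 0.405 with an estimated correlation). The counts adjusted over the list alone were 9 and 2, and the call was lost without Vector replicate 1 (adjusted p = 0.0699), OE replicate 1 (0.065) or 3 (0.0603) and with equal totals (0.0651). NRF2 targets were divided, 7 of 26 higher and 7 lower, and 8 and 9 adjusted over the list alone, with SRXN1 rising from 55.2 ± 0.57 to 87.9 ± 1.21 FPKM and GPX2 falling from 39.8 ± 2.26 to 20.8 ± 1.01 FPKM (SD, n = 3 each; adjusted p = 0.637). Of 18 lysosome and autophagy genes 6 rose and 2 fell, and 6 and 3 adjusted over the list alone, the autophagy receptor gene SQSTM1 (log2 change 0.41) and MAP1LC3B (0.48) among the rises (camera adjusted p = 0.392, fry adjusted p = 0.0172 toward higher values). Of 23 epithelial genes 6 rose, KRT19 and TJP1 among them, and 10 fell, CLDN3 and RAB25 the most, with the same counts adjusted over the list alone (adjusted p = 0.189). Iron handling genes had 2 higher and 5 lower of 23, and 3 and 5 adjusted over the list alone, with FTL (log2 change 0.16) and NCOA4 (0.23) rising and HEPH (-0.47) and CYBRD1 (-0.35) falling (adjusted p = 0.348). Of 67 nuclear-encoded respiratory chain genes 5 fell, UQCR10 and NDUFA13 the most, and 0 adjusted over the list alone (adjusted p = 0.016; adjusted p = 0.504 with an estimated correlation). That list was lost without Vector replicate 2 (adjusted p = 0.109) or OE replicate 1 (0.0694) and with equal totals (0.0776). Single calls were lost without at least 1 library for ANKRD37, with an adjusted p up to 0.0715 without Vector replicate 2, EGLN3, up to 0.0984 without Vector replicate 1, FTL, up to 0.0762 without Vector replicate 2, UQCR10, up to 0.069 without Vector replicate 2, and NDUFA13, up to 0.122 without OE replicate 1.

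Markers of differentiated colonocytes, goblet cells and endocrine cells fell in 3 of 5 measured cases in the OE line, FABP1, ALPI and, named after its value was seen, TFF3, with 4 lower adjusted over the list alone (adjusted p = 0.00302; adjusted p = 0.121 with an estimated correlation), while limma called 0 of 4 in the knockdown, with 1 lower adjusted over the list alone and 1 at an unadjusted p under 0.05. In the OE line glycolysis genes had 3 of 23 higher and 5 lower, and 5 and 5 adjusted over the list alone, ALDOC (log2 change -0.39) and HK2 (0.26) being examples (adjusted p = 0.851). Fatty acid genes had 3 of 17 higher and 2 lower, and 4 and 2 adjusted over the list alone, ELOVL1 (0.33) rising and SCD (-0.30) falling (adjusted p = 0.779), and glycerol-3-phosphate and triglyceride genes 2 of 23 higher and 3 lower, and 3 and 4 adjusted over the list alone, AQP3 (-0.70) falling (adjusted p = 0.851). NF-kB and inflammatory genes had 2 of 15 higher and 2 lower, and 3 and 2 adjusted over the list alone, NFKB2 (0.34) and NFKBIZ (-0.40) (adjusted p = 0.779), and mesenchymal genes 1 of 11 higher and 2 lower, S100A4 (-0.81) and THBS1 (-0.49), with 1 and 4 adjusted over the list alone (adjusted p = 0.172). Of the markers of other cell types, 2 leukocyte, 1 fibroblast or endothelial and 3 hepatocyte or neural genes passed the filter, too few for a test; CD14, PDGFRB and SERPINA1 fell and TUBB3 rose in the OE line, the call of PDGFRB being lost without Vector replicate 1 or 3 or OE replicate 1 (adjusted p up to 0.0633). In the knockdown 2 leukocyte, 0 fibroblast or endothelial and 3 hepatocyte or neural genes passed the filter, and limma called 0 of them, with 1 leukocyte gene at an unadjusted p under 0.05. In the knockdown limma called 0 members of the glycolysis, fatty acid, hypoxia, iron, lysosome, NF-kB, mesenchymal, DNA replication, respiratory chain, mitochondrially encoded, cholesterol and heat shock lists, where 1, 5, 7, 6, 3, 3, 3, 1, 3, 1, 4 and 4 had an unadjusted p under 0.05. These lists did not pass, with adjusted p-values from 0.0659 to 0.881; adjusted over the list alone, 2 fatty acid and 2 mesenchymal genes were lower and 2 heat shock genes higher. Without shGPD1L replicate 3 the epithelial, DNA replication, mitochondrially encoded, heat shock and lysosome lists passed (adjusted p = 3.52e-05, 0.00349, 0.0447, 0.0469 and 0.0178; adjusted p = 0.324, 0.218, 0.7, 0.474 and 0.474 with an estimated correlation), DNA replication genes lying at -0.492 in that library against 0.116 and 0.116. ELF3 fell among 23 epithelial genes (log2 change -0.79, list adjusted p = 0.124), TNFRSF19 among 20 Wnt targets (list adjusted p = 0.18) and GPD1L itself among 22 glycerol-3-phosphate genes (list adjusted p = 0.869). Adjusted over the list alone, 1 epithelial gene was lower, 1 Wnt target higher and 1 lower, and 1 glycerol-3-phosphate gene higher and 2 lower. In the knockdown the camera direction was up and the mean below 0 for glycolysis and mesenchymal genes, and the median was above 0 and the mean below for iron and mesenchymal genes. In the OE line the median was above 0 and the mean below for glycolysis genes, and the reverse held for fatty acid genes.

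The median log2 change of 10 clock output and repressor genes was above 0 in both comparisons, 0.22 in the knockdown, with PER1 and DBP called, and 0.67 in the overexpression, with 8 called, among them NR1D1 (1.43), BHLHE41 (0.97), NR1D2 (0.87) and PER1 (0.86). A response of this list that follows the GPD1L level would have opposite signs in the comparisons. Both medians were above 0 (SE over libraries 0.0175 and 0.0471), the lower being 0.22, and PER1 and DBP were called higher in both. The list was chosen after some of its genes were seen to rise in both, so these values cannot decide for or against such a response. Whether the rise itself is general was not tested. Library scaling is argued against, since with median-of-ratios scaling the lower median was 0.26 and 2 times the largest shift of all genes 0.139. A shift of clock phase between the lines at harvest cannot be told apart from other explanations, since ARNTL, NPAS2, CLOCK and NFIL3, expected to be lower under it, went both ways in the overexpression, with a median of -0.10, NPAS2 and NFIL3 falling and CLOCK rising. In the knockdown they were at -0.49, -0.15, -0.31 and -0.12, with a median of -0.23 (SE over libraries 0.129), in the direction such a shift predicts; limma called 0 of them there, with 2 at an unadjusted p under 0.05, and called ARNTL and CLOCK lower without shGPD1L replicate 3 (adjusted p = 0.0105 and 0.0357).

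Of the genes called with a 2-fold change, 6 share exons with another listed gene on the same strand, and for 4 the gene's change exceeded the spread of its partner. Reads moved between gene models would give opposite changes of the gene and its partner. The median over these 4 of the partner change divided by the gene change in exon coverage was -0.393, with 1 at or under -0.5, and with a value of -0.596 for SH3BGR and its partner WRB-SH3BGR, -0.443 for the MATR3 identifiers (MATR3.ENSG00000015479), -0.342 for AC118553.2 and, named after its value was seen, -0.000795 for AL662899.2. The partners of AC118553.2 and AL662899.2 changed by less than their SD within groups. The genes left out of the median, TRIM39-RPP21 and SYS1-DBNDD2, had ratios of -4.89 and -4.29. Their partners moved against them by more than the SD of the partners within groups, the direction that moved reads would give. With 4 genes, moved reads and a change of the gene itself cannot be told apart for the set, so these changes may be of either kind.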
